A study of Melospiza melodia with 33 samples.

How the data were processed

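Whole blood of wild adult males of the song sparrow, Melospiza melodia, was profiled by RNA sequencing in 33 libraries from 25 birds. Per the labels' protocols, total RNA was purified from blood and treated with DNase, mRNA was enriched by its poly(A) tail, libraries were made with a KAPA HyperPrep kit, and paired-end reads were produced on a NovaSeq X Plus. Haemoglobin transcripts were not depleted; the protocol states that more reads were collected in place of depletion. The submitters' processing notes name fastp, a read trimmer, and STAR, a spliced aligner. Their versions, the counting program, its strand setting, the annotation and the genome build are not given in the sources used here. The batch label is the same for all 33 libraries.

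The deposited files hold raw counts per gene, 1 file per library, with 21141 gene rows that are the same in every file. The values were whole numbers with no row for unassigned reads, and totals differed between libraries, so they were treated as counts without normalization by the authors. Gene symbols were used as the files give them. Of the 21141 rows, 20961 carried a symbol found in the RefSeq gene table of assembly bMelMel2.pri, which was used only for names and for which genes neighbour each other; the other 180 rows were numbered tRNA copies. A total of 8073 rows are named by a LOC number alone. How reads shared by near-identical copies were counted is not given in the sources used here, so values of multigene families, globins included, are uncertain in how they divide between copies, and overlapping or antisense genes cannot be told apart without the strand setting. Total counts per library ran from 64.7 to 103.7 M (mean 83.1 ± 7.93 SD, n = 33), and 12766 to 15472 genes had at least 1 count.

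Groups were taken from the labels: 12 libraries after playback of foreign song, 11 after local song and 10 from baseline birds that had no trial. The comparisons were fixed before the data were examined, with their samples, covariates, gene lists, rule for named genes and processing alternatives. Foreign and local song were compared within the 8 birds that had both, in 1 fit with the bird as a block and the trial (first or second) as a term; the trial coefficient of that fit compared second with first trials. Each song was compared with baseline in a fit of those 2 groups alone, in which each bird label appears once. The bird numbers in the labels pair the libraries. Libraries of 1 bird were checked for deviating together by the Pearson correlation across genes of log2 CPM centred on the means of the song by trial groups, against re-pairings of the second libraries (40320 pairings, one-sided permutation test). The 8 own pairs had a mean r of 0.457, against a mean of 0.000484 over the re-pairings (p = 2.48e-05, the smallest the re-pairings can give).

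Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr on the groups of each fit (minimum count 10, minimum total count 15), trimmed mean of M-values (TMM) normalization, robust dispersion estimates and the quasi-likelihood test, with Benjamini-Hochberg adjustment and a threshold of 0.05 with no fold minimum. Log2 fold changes are given ± a standard error derived from the test, the absolute log2 fold change divided by the square root of its F. It restates the test and is no separate measure of spread. CPM values are counts per M of TMM-scaled library size, and group means are given ± SD. Group means and counts of birds or libraries use the scaling of each fit. CPM of single libraries and the figures of CPM use a scaling over all 33 libraries, so a count near a tie can differ between them. Log2 CPM values used a prior count of 1.

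A set of 20 gene lists was written before the data were examined. They covered blood cell types (erythroid, heterophil granulocyte, thrombocyte, T cell, B cell and monocyte markers), and proliferation, immediate early, glucocorticoid response, heat shock and chaperone, inflammatory NF-kB, interferon response, circadian clock, steroid and monoamine signalling, glycolysis and hypoxia, oxidative stress, nuclear-encoded oxidative phosphorylation, ribosomal protein and proteasome genes. A list of mitochondrially encoded genes had 0 members among the gene rows, so 19 lists were tested. Each was tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of 1 comparison, and beside it with camera at an estimated correlation and with fry (limma 3.58.1). In addition, a list score, the mean log2 CPM of the members, was compared per bird by a two-sided exact permutation test over the 256 sign flips of 8 pairs, or against baseline by a two-sided permutation test with 100000 resamples. These score tests were adjusted by Benjamini-Hochberg over the 19 lists. A gene was named when it passed the threshold with an average log2 CPM of at least 0 and a symbol (up to 12 per direction by smallest p). Where fewer than 5 passed in a direction, the 5 with the smallest p were named as not passing. Members of a called or blood cell list with the smallest p (up to 4) and the 5 most abundant genes were named as well.

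No haemoglobin gene is named as such in the gene rows, so the share of counts in the 10 most abundant genes, fixed as an alternative before the data were examined, stands in for the haemoglobin share. Other alternatives were the fit without the bird block, the bird as a random block in limma-voom, DESeq2 1.42.0, limma-voom, median-of-ratios size factors, no filter or a stricter filter (10 CPM in 8 libraries), a blood cell marker covariate, first trials only, and leaving out birds, stimulus pairs or libraries with fewer lanes. Alternatives chosen after seeing the data removed the 3 most abundant genes or, against baseline and for list tests and named genes, left out libraries whose labels or profiles were in doubt, or each library in turn. A single simulated set of counts per fit held 200 genes changed 1.5-, 2- or 4-fold and, besides them, monocyte list genes raised 1.5-fold. With so many genes changed the adjusted threshold is easier to reach, so the shares do not apply to a few changed genes. The quasi-likelihood test recovered 46.3% of 2-fold changes in the foreign versus local fit (11402 genes) and 59.7% in the second versus first fit (11239 genes). It recovered 47.8% in the foreign versus baseline fit (11678 genes) and 29.9% in the local versus baseline fit (11572 genes). At 4-fold the shares were 93.9%, 78.8%, 92.4% and 83.3%, and at 1.5-fold 13.4%, 11.9%, 7.46% and 5.97%, in the same order. No 2 libraries of a group agreed within sampling noise. The lowest chi-square per degree of freedom between libraries was 195 among the local song libraries, 206 among the baseline libraries and 220 among the foreign song libraries. Some genes that the naming rule selects are not reported here.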

Results

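Blood was collected from male song sparrows in Linesville, Pennsylvania, where territorial intrusions were simulated by playing songs recorded at the same place (local song, stimuli 2, 3 and 6) or songs from Millbrook, New York (foreign song, stimuli 1, 4 and 5). The data comprise 12 foreign song libraries, 11 local song libraries and 10 baseline libraries of birds that had no trial. Of the birds played to, 8 had a library after each song. Local song came first in 4 of these and foreign song first in the other 4. The order followed the stimulus in part: paired birds given stimuli 3 and 4 all heard 3 first, and those given 5 and 6 all heard 5 first. In those birds song, trial and stimulus cannot be told apart. Each stimulus was played to several birds, so birds that shared one are not independent samples of a song's origin. Mean depth was 85.6 ± 7.53 M counts in foreign song, 79.0 ± 7.14 M in local song and 84.6 ± 8.16 M in baseline libraries (SD, n = 12, 11 and 10).

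A few genes took a large share of the counts in this blood, in which red cells are nucleated. The 3 most abundant, LOC134426298 (13.2% of counts on average), LOC134431771 (11.7%) and LOC134426297 (6.05%), held 30.9% ± 6.97 together (SD, n = 33). LOC134426298 and LOC134426297 lie next to each other, beside PGAP6. LOC134417358 (1.65%) and LOC134427256 (0.938%) followed. The 10 most abundant genes held 36.2% ± 7.33 of the counts, and no difference in this share was detected between songs within birds (difference 0.56 percentage points, exact permutation p = 0.898, n = 8 pairs) or between second and first trials (−5.06, exact permutation p = 0.211). Against baseline, the difference was −1.37 percentage points for foreign song (permutation p = 0.658) and 0.814 for local song (permutation p = 0.812). The 4 differences were −2.21 (p = 0.531), −2.93 (p = 0.422), −1.88 (p = 0.562) and 2.47 (p = 0.435) without the libraries labelled 8439, in the same order. These tests were two-sided and not adjusted for each other.

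The 2 libraries of a bird resembled each other in 7 of the 8 birds played both songs. Own-pair correlations across genes were 0.363 to 0.649 in these 7 birds, each above the correlation with any second-trial library of another bird. The libraries labelled 8439 were the exception, with r = −0.0665. Genes are not independent replicates, so these values describe likeness and carry no p across genes. The labels of 8439 are in doubt, so values without them are given below for the gene counts and for several list scores, list calls and genes that they move.

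**Figure D1:**
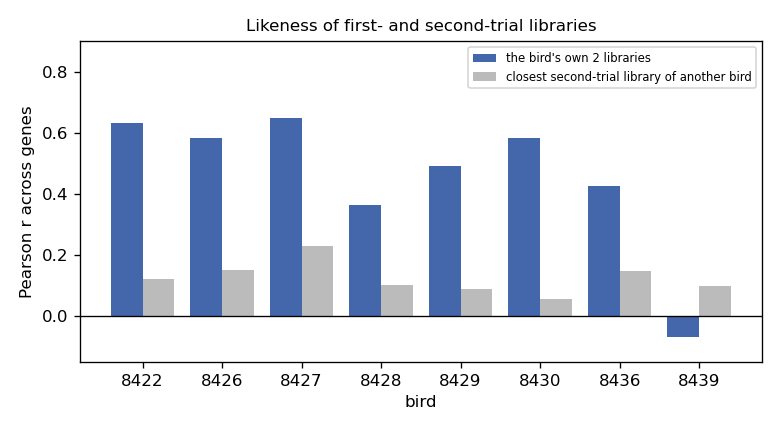
Pearson r across genes (y axis) between the first- and second-trial libraries of each bird (x axis), as blue bars, and between the bird's first library and the closest second-trial library of another bird, as grey bars. The blue bar is the higher one in 7 of 8 birds and lies at −0.0665 for 8439.

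Foreign song was compared with local song within birds to ask whether the origin of an intruder's song went with a difference in blood transcripts. Among the genes of smallest p, SPI1, the transcription factor that directs myeloid development, averaged 12.1 ± 5.66 CPM after foreign and 19.7 ± 8.85 after local song and was lower in 8 of 8 birds (log2 fold change −0.70 ± 0.16). LSP1, an actin-binding protein of leukocytes, was lower in 8 of 8 birds as well (−0.79 ± 0.19). No single gene passed the threshold.

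Of 11629 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 0 passed. The lowest adjusted p was 0.775, which all genes named for this comparison from the edgeR fit share. At an unadjusted p under 0.05 there were 486 genes, 94 higher and 392 lower after foreign song, where chance gives 581. The counts were 0 and 493 without the libraries labelled 8439. DESeq2 called 4 genes, CADM2, LOC134424120, LOC134424122 and LOC134432362, all lower (named after their values were seen; 837 genes at an unadjusted p under 0.05), and limma-voom with the bird as a random block called 0 (796 genes). Others of the smallest p were SRPK2, a kinase of splicing factors (−0.91 ± 0.22, lower in 8 of 8 birds), IQGAP3 (−0.89 ± 0.23) and LGMN, a lysosomal endopeptidase (−0.75 ± 0.20). Among genes with positive values were EPAS1, a hypoxia-inducible transcription factor (0.52 ± 0.19; 730 ± 339 against 522 ± 244 CPM, higher in 7 of 8 birds), MARF1 (0.47 ± 0.16), HYAL2, a hyaluronidase (0.66 ± 0.25), PLS1, an actin-bundling plastin (0.73 ± 0.25), and SFXN1, a mitochondrial serine carrier (0.73 ± 0.27). In first trials alone, where each bird is present once, the values of EPAS1 (−0.58), PLS1 (−0.67) and SFXN1 (−0.987) turned negative and that of IQGAP3 (0.15) turned positive.

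Of the 19 gene lists, 8 were called by camera at the preset correlation, and 0 by camera with an estimated correlation or by fry. Monocyte markers were lower after foreign song in 16 of 18 members (camera adjusted p = 3.8e-10; adjusted p = 0.541 with an estimated correlation). SPI1 and LGMN are its leading members, and 6 members passed when adjusted over the list alone, against 0 over all genes. The monocyte score was lower in 7 of 8 birds, by −0.579 on the log2 scale (two-sided exact permutation p = 0.0234, adjusted p = 0.26). Without the libraries labelled 8439 it was −0.344 (7 pairs, exact permutation p = 0.0469, adjusted p = 0.416).

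T cell markers were lower in 21 of 23 members (camera adjusted p = 9.86e-06), among them BCL11B, a T lineage transcription factor (−1.07 ± 0.47), and CD8B, a co-receptor chain (−0.63 ± 0.28). Heterophil granulocyte markers were lower in 10 of 12 members, with ALOX5AP of leukotriene synthesis at −0.54 ± 0.21. B cell markers were lower in 16 of 21, with CD40 at −0.67 ± 0.28 and EBF1 at −1.15 ± 0.49. Erythroid markers were higher in 19 of 23, with TFRC, the transferrin receptor, at 0.41 ± 0.21 and UROS of haem synthesis at 0.33 ± 0.18. The camera adjusted p of these 3 lists was 0.0107 each, and that of all 4 was 0.541 with an estimated correlation. First trials alone compare different birds (8 foreign and 7 local song libraries), and no list was tested in that fit. No member named here kept its sign there. BCL11B (0.0023) and ALOX5AP (0.016) showed almost no difference, while CD8B stood at 0.63, CD40 at 0.50, EBF1 at 0.29, TFRC at −0.25 and UROS at −0.18. BCL11B turned as well with a covariate for white cell and thrombocyte markers (0.035), and CD8B without the bird block in all 23 song libraries (0.064). The local song library labelled 8439 held BCL11B at 26.3 CPM and EBF1 at 9.80 CPM, against at most 3.12 and 2.48 CPM in the local song libraries of the other 7 birds. Without the pair labelled 8439 BCL11B stood at −0.62, EBF1 at −0.71 and UROS at 0.19, and the heterophil score difference was −0.176 in place of −0.332. The 4 lists were still called (adjusted p at least 0.674 with an estimated correlation). B cell markers lost the call without bird 8428 (0.0573) and heterophil (0.0521) and erythroid markers (0.0521) without bird 8429.

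Inflammatory NF-kB genes were lower in 22 of 30 members (camera adjusted p = 0.0138), led by TNFAIP8 (−0.73 ± 0.26) and TLR7, a sensor of single-stranded RNA (−0.82 ± 0.30). Heat shock and chaperone genes were higher in 22 of 30 (adjusted p = 0.0279), with HSPA2 at 0.32 ± 0.19 and DNAJB4 at 0.30 ± 0.18. Proteasome genes were higher in 25 of 37 (adjusted p = 0.0262), with PSME4 at 0.30 ± 0.14 and PSMG1 at 0.37 ± 0.21. With an estimated correlation the adjusted p was 0.541 for the NF-kB and heat shock lists and 0.689 for the proteasome list. Thrombocyte markers, with CD9 at −0.50 ± 0.26 and GATA2 at −0.46 ± 0.31, missed the threshold (camera adjusted p = 0.0517). They were called as lower in 5 of 8 fits with 1 bird left out (adjusted p 0.00251 to 0.0375; at least 0.61 with an estimated correlation). Without the pair labelled 8439 their score difference went from −0.223 to 0.0203. Glucocorticoid response (0.0909), ribosomal protein (0.0983), oxidative phosphorylation (0.0983), oxidative stress (0.12), immediate early (0.167), circadian clock (0.252), glycolysis and hypoxia (0.268), interferon response (0.672), proliferation (0.835) and steroid and monoamine signalling genes (0.951) did not pass either. In first trials HSPA2 (−0.70) and DNAJB4 (−0.22) turned negative, as did HSPA2 without the bird block in all 23 song libraries (−0.011) and PSMG1 with the marker covariate (−0.059). GATA2 turned positive with that covariate (0.30) and without stimuli 5 and 6 (0.055). Without the pair labelled 8439 the score differences went from 0.0835 to 0.00311 for heat shock, from −0.267 to −0.144 for NF-kB and from 0.0996 to −0.0169 for proteasome genes. HSPA2 then stood at 0.14, DNAJB4 at 0.19, TNFAIP8 at −0.48, PSMG1 at 0.17, CD9 at −0.31 and GATA2 at −0.13. The list calls depended on single birds. They numbered 3 without bird 8430, namely monocyte, T cell and heterophil markers. Heat shock (adjusted p = 0.489), NF-kB (0.121) and proteasome genes (0.633, now lower) were no longer called without the libraries labelled 8439. In that fit ribosomal protein (2.96e-14) and oxidative phosphorylation genes (0.000243) were called as lower. With an estimated correlation the adjusted p of these last 2 was 0.674 and 0.707. Both were called in the other direction, as higher, without bird 8422, 8426, 8428 or 8436. The adjusted p was 0.0206, 0.0122, 2.33e-05 and 0.000543 for ribosomal protein and 0.0349, 0.01, 0.00176 and 0.000543 for oxidative phosphorylation genes, and at least 0.61 with an estimated correlation. In 1 fit each, glucocorticoid response genes were called as lower (0.00491, without 8428) and interferon response (0.00575, without 8427) and oxidative stress genes (0.029, without 8436) as higher (at least 0.302 with an estimated correlation).

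**Figure D2:**
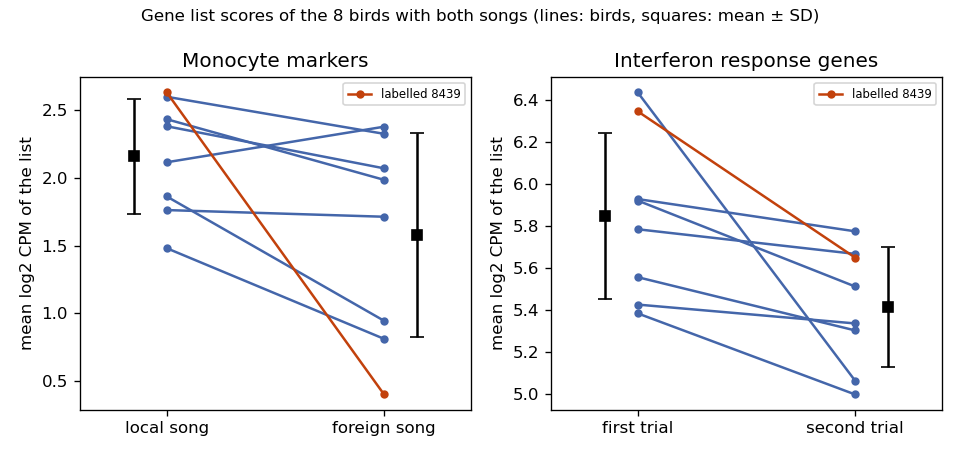
Gene list scores (mean log2 CPM of the list, y axis) of the 8 birds with both songs: monocyte markers after local and foreign song (left) and interferon response genes in first and second trials (right). Lines join the libraries of a bird, orange marks the libraries labelled 8439, and squares with bars give the mean ± SD; the monocyte score was lower after foreign song in 7 of 8 birds and the interferon score lower in second trials in 8 of 8.

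Second trials were compared with first trials within the same 8 birds, to see whether recapture and a second playback went with a difference. Interferon response genes stood lower in second trials in 23 of 26 members (camera adjusted p = 8.52e-13; adjusted p = 0.575 with an estimated correlation). IRF1, a transcription factor induced by interferon that was counted here in the inflammatory NF-kB list, averaged 552 ± 117 CPM in second and 887 ± 262 in first trials (log2 fold change −0.65 ± 0.17, lower in 7 of 8 birds). SOCS1, an inhibitor of cytokine signalling, stood at −0.84 ± 0.19 (lower in 6 of 8 birds), and IFI35, an interferon-induced protein, at −0.70 ± 0.19 (lower in 8 of 8). These bird counts use log2 CPM as scaled in this fit, and a bird with a small difference can fall on either side under another scaling.

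None of these passed as a single gene: with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment 0 of 11629 genes did, and the lowest adjusted p, 0.633, is that of every gene named for this comparison from the edgeR fit. At an unadjusted p under 0.05 there were 666 genes, 440 higher and 226 lower, where chance gives 581. The counts were 0 and 515 without the libraries labelled 8439. DESeq2 called 6 genes (1105 at an unadjusted p under 0.05): DUSP15, FRMD4A and SOCS1, and, named after their values were seen, LOC134416526, NRG2 and ST6GALNAC1. The random-block limma-voom fit called 0 (1265 genes). DUSP15, a dual-specificity phosphatase, was lower in 8 of 8 birds (−1.30 ± 0.29), as was FBXO2, a substrate receptor of a ubiquitin ligase (−0.67 ± 0.18). With positive values came FRMD4A, a scaffold protein of epithelial polarity (1.39 ± 0.34), ZFHX3, a zinc finger and homeobox transcription factor (1.15 ± 0.29), ZNF618 (0.73 ± 0.19, higher in 8 of 8 birds), PPP1R3E, a glycogen-targeting phosphatase subunit (0.91 ± 0.26), and POLA2, a subunit of DNA polymerase alpha (0.72 ± 0.21, higher in 8 of 8).

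Camera at the preset correlation called 8 lists, and 0 were called with an estimated correlation or by fry. In the interferon response list 15 members had an unadjusted p under 0.05, and 9 passed when adjusted over the list alone, against 0 over all genes. The interferon score was lower in 8 of 8 birds, by −0.435 (two-sided exact permutation p = 0.00781, the smallest 8 pairs can give; adjusted p = 0.148). Without the libraries labelled 8439 it was −0.398, lower in 7 of 7 birds (exact permutation p = 0.0156, the smallest 7 pairs can give; adjusted p = 0.297). The inflammatory NF-kB list, which holds IRF1 and shares SOCS1 with the interferon list, was not called (camera adjusted p = 0.405) but was called as lower without the libraries labelled 8439 (0.0118; adjusted p = 0.416 with an estimated correlation), and these 2 members passed when adjusted over the list alone, against 0 over all genes.

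All 70 ribosomal protein genes tested had negative values (camera adjusted p = 8.62e-24), with RACK1 at −0.49 ± 0.22 and RPL35 at −0.44 ± 0.20. Oxidative phosphorylation genes were lower in 51 of 54 members (8.52e-13), with ATP5F1B of ATP synthase at −0.57 ± 0.21 and NDUFV1 of complex I at −0.51 ± 0.21. Proteasome genes were lower in 31 of 37 (3.02e-06), with PSMD6 at −0.38 ± 0.18 and PSMC3 at −0.40 ± 0.21. Heat shock and chaperone genes were lower in 26 of 30 (0.000193), with HSPA5, a chaperone of the endoplasmic reticulum, at −0.28 ± 0.13. Oxidative stress genes were lower in 22 of 29 (0.00209), with SOD1, superoxide dismutase, at −0.49 ± 0.23; MSRA, a methionine sulfoxide reductase, was at 0.47 ± 0.20. All 5 lists had an adjusted p = 0.575 with an estimated correlation. Their scores were higher in second trials in 3 of 8 birds for oxidative phosphorylation and in 2 of 8 for the other 4. Without the pair labelled 8439 the 5 lists were still called (adjusted p at least 0.403 with an estimated correlation), but the score differences went from −0.424 to −0.203 (ribosomal protein), from −0.29 to −0.14 (oxidative phosphorylation), from −0.202 to −0.1 (proteasome), from −0.151 to −0.0803 (heat shock) and from −0.148 to −0.076 (oxidative stress). RACK1 then stood at −0.27, RPL35 at −0.26, ATP5F1B at −0.35, NDUFV1 at −0.30, PSMD6 at −0.19, PSMC3 at −0.17, SOD1 at −0.27 and MSRA at 0.30.

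Thrombocyte markers were higher in 21 of 23 members (0.00041), with PDLIM1 at 0.42 ± 0.22, and monocyte markers were higher in 16 of 18 (0.00803), with LY86 at 0.57 ± 0.23 and C1QB, a complement chain, at 0.60 ± 0.25. Both had an adjusted p = 0.629 with an estimated correlation, and both lost the call without the libraries labelled 8439 (0.078 and 0.141; score differences from 0.319 to 0.0897 and from 0.335 to 0.0642, PDLIM1 at 0.22 and LY86 at 0.34). Monocyte markers lost it without bird 8430 too (0.11). Heterophil markers (camera adjusted p = 0.174; ANXA1 0.63 ± 0.27, TLR4 0.59 ± 0.30), T cell markers (0.405; CD8A −0.91 ± 0.38, BCL11B 0.81 ± 0.47), B cell markers (0.302; CD79A −0.51 ± 0.22, XBP1 −0.45 ± 0.20) and erythroid markers (0.419; LMO2 −0.32 ± 0.19, EPB42 −0.31 ± 0.19) did not pass. Without the pair labelled 8439 TLR4 stood at 0.32, BCL11B at 0.35, XBP1 at −0.25, LMO2 at −0.15 and EPB42 at −0.16. Nor did proliferation (0.0711), glucocorticoid response (0.302), steroid and monoamine signalling (0.443), immediate early (0.701), circadian clock (0.969) or glycolysis and hypoxia genes (0.969). With 1 bird left out, heterophil markers (without 8426 or 8428) and proliferation genes (without 8426 or 8436) were called as higher in 2 of 8 fits each and B cell markers as lower in 1 (without 8427; adjusted p 0.00626 to 0.0463, at least 0.396 with an estimated correlation).

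Foreign song was compared with baseline birds to ask whether blood after a foreign song trial differed from that of birds without a trial. The song libraries here and in the local song comparison include second trials of birds that had already heard the other song. PFKFB3, the enzyme that sets the level of an activator of glycolysis, averaged 641 ± 217 CPM after foreign song and 381 ± 89.9 in baseline birds (SD, n = 12 and 10; log2 fold change 0.75 ± 0.17), above the baseline median in 12 of 12 libraries. RELL2, a membrane protein of the RELT family, stood at 184 ± 132 against 73.4 ± 29.1 CPM (1.33 ± 0.34), and ENTPD1, the ectonucleotidase that breaks down extracellular ATP and ADP, at 7.09 ± 3.84 against 3.37 ± 1.01 CPM (1.07 ± 0.29). None of the 3 passed the threshold.

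Of 11817 genes, 0 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. There were 842 genes at an unadjusted p under 0.05, 303 higher and 539 lower, where chance gives 591. Without the library labelled 8439 the counts were 0 and 997, and without baseline 8450 as well 0 and 1536. DESeq2 called 1 gene, DBT (979 genes at an unadjusted p under 0.05), and limma-voom called 0 (648 genes). With edgeR the adjusted p was 0.503 for DBT and 0.687 for the other 9 genes of smallest p, which included CLMN (1.54 ± 0.43) and ERCC8, a protein of transcription-coupled DNA repair (−0.84 ± 0.22, below the baseline median in 12 of 12 libraries). The lowest values came from genes high in 1 or a few baseline birds. DBT, a subunit of the branched-chain keto acid dehydrogenase, stood at −5.11 ± 1.00; it was at 96.9, 90.0 and 123 CPM in baseline birds 8443, 8447 and 8448 and at 1.61 CPM or less in the other 7. SHROOM2, an actin-binding protein (−3.85 ± 0.89), SIK2, a salt-inducible kinase (−3.31 ± 0.83), and NSG1, a protein of neuronal vesicles (−3.38 ± 0.87), were each high in 1 baseline bird and stood at −0.64, −0.53 and −0.44 without it.

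**Figure D3:**
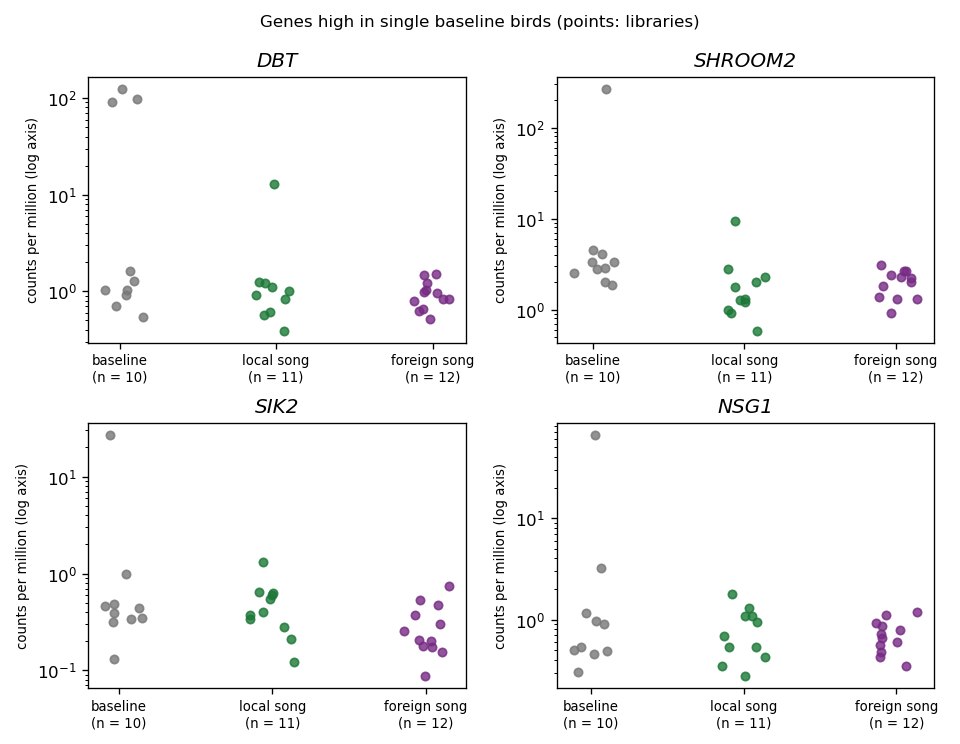
CPM (log axis) of DBT, SHROOM2, SIK2 and NSG1 in each library by group (x axis: baseline n = 10, local song n = 11, foreign song n = 12); each point is a library, and a library with 0 counts is not drawn. SHROOM2, SIK2 and NSG1 each have 1 baseline bird far above the rest, at 264, 27.0 and 66.1 CPM, and DBT has 3 at 90.0 to 123 CPM.

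Camera at the preset correlation called 4 lists against baseline, and 0 were called with an estimated correlation or by fry. Heat shock and chaperone genes were higher after foreign song in 23 of 30 members (adjusted p = 1.38e-06; adjusted p = 0.776 with an estimated correlation), with HSPA4 at 0.42 ± 0.15 and STIP1, a co-chaperone of Hsp70 and Hsp90, at 0.50 ± 0.18. The heat shock score was higher by 0.222 (two-sided permutation p = 0.0318, adjusted p = 0.604), above the baseline median in 9 of 12 libraries. T cell markers were lower in 21 of 24 members (7.52e-05), with CD4 at −1.04 ± 0.35 and CD247, a T cell receptor chain, at −0.94 ± 0.34. Oxidative phosphorylation genes were lower in 44 of 54 (0.041), with NDUFB2 at −0.58 ± 0.23 and SDHB at −0.37 ± 0.17, and inflammatory NF-kB genes in 24 of 31 (0.0474), with the cytokine IL6 at −1.23 ± 0.44 and SOCS3 at −0.67 ± 0.36. These 3 lists had an adjusted p = 0.871 with an estimated correlation.

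Baseline bird 8448 had a T cell score of 3.21 mean log2 CPM, against at most 1.59 in the other baseline birds, and without it the T cell (0.101) and NF-kB (0.278) lists were not called. In first trials alone the oxidative phosphorylation list was not called and pointed up (0.777), and the NF-kB list was not called (0.3); the latter was also lost without the library labelled 8439 (0.132). With each of the 22 libraries left out in turn, the NF-kB call was lost in 10 fits and the oxidative phosphorylation call in 9 (adjusted p up to 0.531), and the T cell call in 1, that without 8448. Lists not called otherwise were called in some of these fits. These were heterophil markers (9 fits) and proteasome genes (2) as lower and ribosomal protein (6) and proliferation genes (3) as higher (at least 0.704 with an estimated correlation). Among the other blood cell lists, heterophil markers (camera adjusted p = 0.0525) included ITGB2 at −0.74 ± 0.33 and ALOX5AP at −0.83 ± 0.37, and erythroid markers (0.494) ANK1 at 0.36 ± 0.16 and UROD at −0.57 ± 0.23. Thrombocyte markers (0.494) included BIN2 at −0.34 ± 0.16 and ITGB3 at −0.65 ± 0.31, B cell markers (0.442) BLK at −0.97 ± 0.48 and VPREB3 at −0.84 ± 0.46 (0.19 with DESeq2 and 0.20 without the libraries labelled 8439 and baseline 8450), and monocyte markers (0.494) IL10RA at −1.07 ± 0.52 and STAB1 at 0.62 ± 0.31. Without bird 8448 ITGB2 stood at −0.36, ALOX5AP at −0.38, BLK at −0.37 and IL10RA at −0.62, without baseline bird 8435 ITGB3 at −0.14, without 8438 SOCS3 at −0.43, and without 8450 SDHB at −0.17 and VPREB3 at 0.17. The glycolysis and hypoxia list, to which PFKFB3 belongs, was not called (0.494) and pointed down, with 21 of 31 members lower. In it 1 member passed when adjusted over the list alone, against 0 over all genes.

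Local song was compared with baseline birds in the same way. ENTPD1 was 2.40-fold higher after local song, at 8.13 ± 2.71 CPM against 3.38 ± 0.947 in baseline birds (SD, n = 11 and 10; log2 fold change 1.26 ± 0.22), above the baseline median in 11 of 11 libraries. It was the 1 gene of 11800 that passed (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0469). With each of the 21 libraries left out in turn it passed in 4 fits and missed the threshold in 17 (adjusted p 0.0199 to 0.158, log2 fold change 1.14 to 1.34). RELL2 stood at 236 ± 169 against 74.0 ± 29.6 CPM (1.67 ± 0.32, adjusted p = 0.149) and MN1, a transcriptional co-regulator, at 6.89 ± 2.48 against 2.87 ± 1.30 CPM (1.26 ± 0.25, adjusted p = 0.157). Both lay above the baseline median in 11 of 11 libraries under the scaling of this fit, and neither passed.

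The adjusted p of ENTPD1 lay between 4.85e-05 and 0.317 over the alternatives. It missed the threshold in first trials alone (0.301) and with the size factors of DESeq2 (0.067), among others, and without the library labelled 8439 (0.0508), and passed with limma-voom (0.044) and DESeq2 (4.85e-05). At an unadjusted p under 0.05 there were 702 genes, 422 higher and 280 lower, where chance gives 590. Without the library labelled 8439 the counts were 0 and 798. DESeq2 called 18 genes (856 at an unadjusted p under 0.05) and limma-voom 1 (547). Without the libraries labelled 8439 and baseline 8450, edgeR called 3 genes, ENTPD1 and MN1 among them, and without the 4 libraries apart on the first principal components 9, with RELL2, ULK2, CLMN and PFKFB3 among them. Among the named genes that did not pass with edgeR were PPP1R14C, an inhibitor of protein phosphatase (2.32 ± 0.52; adjusted p = 0.327), GK5, a glycerol kinase family member (1.11 ± 0.26), and ULK2, an autophagy kinase (1.05 ± 0.25; both adjusted p = 0.366). On the lower side stood NDUFB10 of complex I (−0.87 ± 0.23), SLC44A1, a choline transporter (−1.02 ± 0.28), YWHAH, an adaptor of the 14-3-3 family (−1.10 ± 0.30), CD8A, a T cell co-receptor chain (−2.72 ± 0.74), and SGO1, a guardian of centromeric cohesion (−3.49 ± 0.96), with an adjusted p of 0.515 each. SGO1 was at 28.9 CPM in baseline bird 8447 and CD8A at 19.2 CPM in baseline bird 8448, against baseline medians of 0.269 and 0.823. Without these birds SGO1 stood at −0.21 and CD8A at −1.04.

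**Figure D4:**
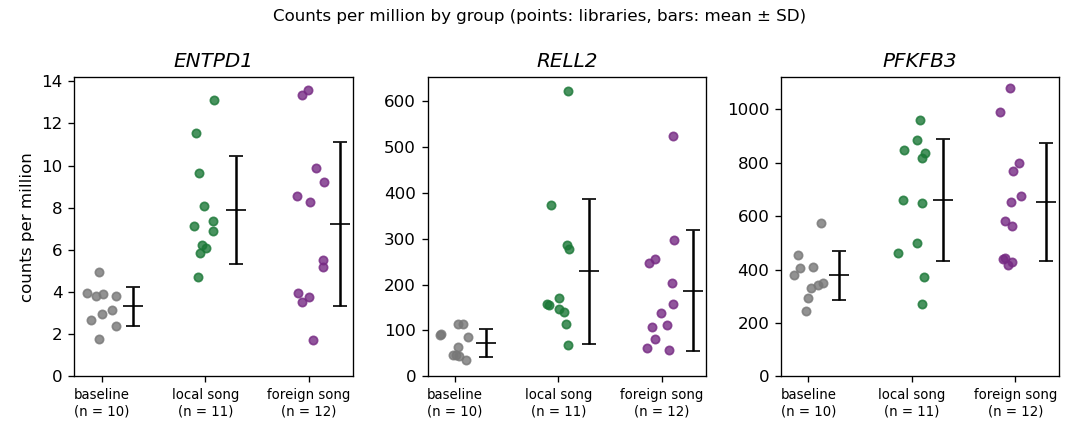
CPM (y axis) of ENTPD1, RELL2 and PFKFB3 in each library by group (x axis: baseline n = 10, local song n = 11, foreign song n = 12), with the mean ± SD of each group as a bar beside the points. ENTPD1 lay between 4.71 and 13.1 CPM in local song libraries and between 1.76 and 4.95 CPM in baseline libraries.

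Camera at the preset correlation called 6 lists for local song, and 0 were called with an estimated correlation or by fry. Glucocorticoid response genes were higher in 26 of 31 members (adjusted p = 0.00149; adjusted p = 0.195 with an estimated correlation), led by ZBTB16 (1.59 ± 0.47) and TSC22D3 (0.68 ± 0.21; 133 ± 49.6 against 82.8 ± 14.4 CPM), both known targets of the glucocorticoid receptor. The glucocorticoid score was higher by 0.23 (two-sided permutation p = 0.0259, adjusted p = 0.493), above the baseline median in 9 of 11 libraries. Immediate early genes were higher in 19 of 30 (0.04; adjusted p = 0.488 with an estimated correlation), with NR4A1 at 1.49 ± 0.48 and CSRNP1 at 1.39 ± 0.48. The local song library of bird 8432 held CSRNP1 at 56.5 and NR4A1 at 10.96 CPM, against at most 13.7 and 3.71 CPM in the other local song libraries. Without it the 2 stood at 0.57 and 0.78. With 1 library left out the immediate early call was lost in 8 of 21 fits (adjusted p up to 0.165). Heat shock and chaperone genes were higher in 24 of 30 (0.000653; adjusted p = 0.683 with an estimated correlation), with STIP1 at 0.52 ± 0.17 and HSPB1 at 1.26 ± 0.51. With an estimated correlation this list was called in first trials alone (0.0388) and without the 4 libraries apart on the first principal components (0.032).

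Monocyte markers were higher in 14 of 19 members (0.000821; adjusted p = 0.488 with an estimated correlation), with VCAN, a matrix proteoglycan, at 1.5 ± 0.43; 3 members passed when adjusted over the list alone, against 0 over all genes. Without the libraries labelled 8439 and baseline 8450 this call was lost (0.186), as it was without baseline 8450 alone (0.0668). T cell markers were lower in 18 of 24 (0.000653; adjusted p = 0.683 with an estimated correlation), with CD8A and TBX21, a regulator of cytotoxic T cells (−1.65 ± 0.51), in front. In this list 2 members passed when adjusted over the list alone, against 0 over all genes, and the call was lost without baseline bird 8448 (0.0915), with TBX21 at −0.72. Interferon response genes were lower in 21 of 26 (0.0119; adjusted p = 0.714 with an estimated correlation), with PARP9 at −0.68 ± 0.35, although the member of smallest p, CD274, an immune checkpoint ligand, stood at 1.34 ± 0.46. Without the 4 libraries that stood apart on the first 2 principal components (local song 8428, 8437 and 8439 and baseline 8450) the monocyte and interferon lists were not called (0.22 each). The interferon call was lost in 3 of 21 fits with 1 library left out, those without local song 8434 (0.0655) and 8437 (0.257) and baseline 8444 (0.201). Of the blood cell lists not called, erythroid markers (0.329) included SLC4A1, the anion exchanger of red cells, at 0.37 ± 0.15 and BPGM at −0.60 ± 0.26, and heterophil markers (0.329) ALOX5 at −1.29 ± 0.57 and ALOX5AP at −0.67 ± 0.34. ALOX5 turned to 0.16 with DESeq2, to 0.037 with the marker covariate and to 0.18 without baseline bird 8448. Thrombocyte markers (0.329) included VWF at 1.19 ± 0.36 and TLN1 at 0.45 ± 0.28, and B cell markers (0.111) BLK at −1.08 ± 0.46 and CXCR5 at −0.67 ± 0.30. Without bird 8448 ALOX5AP stood at −0.24 and BLK at −0.50, and without the library labelled 8439 TLN1 at 0.29. Without the library labelled 8439 B cell (0.0287) and inflammatory NF-kB genes (0.0325) were called as lower and ribosomal protein genes as higher (1.8e-09), each with an adjusted p = 0.618 with an estimated correlation. Over the 21 fits with 1 library left out, lists not called otherwise were called as lower for proteasome (9 fits), B cell (5), NF-kB (4) and oxidative phosphorylation genes (1) and as higher for ribosomal protein genes (5) and thrombocyte markers (1), with an adjusted p of at least 0.618 with an estimated correlation.

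The fold changes of both songs against baseline were correlated across 12296 genes (r = 0.594, covariance 0.0852). Both comparisons use the same baseline libraries, and 8 birds are in both song groups. Simulated unchanged groups against shared controls gave r = 0.53 and a covariance of 0.0722 over 200 draws, and with the baseline libraries split between the comparisons, over 252 splits, r was 0.0725 and the covariance 0.0146. In first trials, where no bird is in both groups, r was 0.403 and the covariance 0.0654 (simulated 0.434 and 0.0743; with split baselines −0.0191 and −0.00521). In all trials the 8 birds in both song groups can raise r beyond what shared controls alone give. The excess of 0.594 over 0.53 is therefore not read as a response common to both songs. Genes are not independent, so no p is given.

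The median, the mean and the direction given by camera differed in sign in no called list. They did so among lists that were not called: interferon, proliferation, circadian clock and steroid and monoamine genes between songs, and inflammatory NF-kB, immediate early, circadian clock and glycolysis genes between trials. Against baseline they did so for erythroid, immediate early, interferon and circadian clock genes after foreign song and for oxidative phosphorylation and glycolysis genes after local song. A note on the form of the deposited file also follows the groups: 9 of 10 baseline libraries carry one wording, against 3 of 12 foreign and 3 of 11 local song libraries. With that note as a covariate edgeR's quasi-likelihood test called 2 genes after foreign song, KIF14 and ST6GALNAC2 (named after their values were seen), and 0 after local song (731 at an unadjusted p under 0.05). Since 9 of 10 baseline libraries carry the same wording, these fits can hardly tell song from the note.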

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

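Tests chosen only after the result was seen were those on genes high in 1 bird, on the labels of 8439 and baseline 8450, on reads of other birds in the local song library labelled 8439, and on whether 1 bird set the interferon difference, along with list tests, list scores and named gene values without 8439 and fits against baseline that left out libraries whose labels or profiles were in doubt or each library in turn.

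Several genes were low in most baseline birds and high in 1: SHROOM2 reached 264 CPM in bird 8442 (median of the 10 baseline birds 3.10), SIK2 27.0 CPM in 8435 (median 0.415), NSG1 66.1 CPM in 8449 (median 0.717) and SGO1 28.9 CPM in 8447 (median 0.269), each farther from its neighbour than Dixon's 95% value allows. A baseline bird has 1 library, so genes were picked in the birds with both songs, where a library held at least 5 CPM and at least 20 times the level of every other bird (all gene rows, taken after filtered genes alone had given fewer picks). Outside 8439 this gave 19 picks of 10 genes in 4 birds, among them PDE11A (54.2 and 38.6 CPM in the libraries of bird 8427) and SHROOM3 (285 and 245 CPM in 8428). The bird's other library stood at a median ratio of 0.933 to the one picked. Most of the 10 genes were picked in both libraries of their bird, so their ratios are reciprocal pairs and the median lies near 1 for that reason. What the picks outside 8439 show is that these 10 genes were high in both libraries, with no ratio under 0.1. For these genes that argues against a one-off event in a single library. A lasting property of the bird, such as a variant near the gene, may account for it. That stays a hypothesis, since no genotype was analysed here. The 2 picks in 8439, whose labels are in doubt, both had a ratio under 0.1. SHROOM2, SIK2, NSG1 and SGO1 could not be tested in this way, since their birds have 1 library each.

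The libraries labelled 8439 stood apart: their own-pair correlation over all filtered genes was −0.0665, against a median of 0.536 in the 8 birds. For each bird 200 genes were chosen anew, for repeatability in the other 7 birds. The pair labelled 8439 thus took part in the choice for every other bird. Over these genes the own-pair correlation was −0.211 for 8439 and 0.677 to 0.888 in the others. Without genes of blood cell composition and weak genes it was −0.14, against at least 0.71, so composition or weak genes are argued against. Over the 200 genes chosen for 8439, the foreign song library with that label correlated at 0.723 with the library labelled baseline 8450. This was the highest of 520 pairs across birds (the next was 0.332). Over all filtered genes, centred on the mean of all libraries, the pair correlated at 0.0753, against 0.24 to 0.635 in the other 7 own pairs and −0.295 in the own pair of 8439. Its chi-square per degree of freedom was 1489, against 153.1 to 557.6 in the other 7 own pairs and 1476 in the own pair of 8439. The chi-square takes in the most abundant genes, and the 10 most abundant held 40.6% of counts in foreign song 8439 and 19.7% in baseline 8450. The low own-pair values of 8439 are what a wrong label would give. A library that is unusual for another reason could give them too, which was not tested. The local song library labelled 8439 had the highest TMM factor of the 33 libraries (2.06) and a share of 20.7% in the 10 most abundant genes. Whether foreign song 8439 and baseline 8450 come from 1 bird stays open, since their correlations and chi-square go both ways. Reads of other birds in the local song library labelled 8439 cannot be told apart either: genes high in 1 other bird stood there at a median of 1.21% of that bird's level, the highest of the 33 libraries, and the 5 birds with 3 or more such genes had medians of 0.29% to 2.07%, but 1 gene of 8431 stood at 13.8%, and the other birds had too few genes or none.

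The pair labelled 8439 gave the extreme value among the 8 birds for many list scores. Foreign minus local song, its difference was −1.92 for thrombocyte markers, −2.23 for monocyte markers, −0.628 for immediate early genes, 0.648 for oxidative stress genes, 1.33 for oxidative phosphorylation, 1.98 for ribosomal protein and 0.915 for proteasome genes, in mean log2 CPM. Second minus first trial, the same pair gave 1.92, 0.628, −0.648, −1.33, −1.98 and −0.915 for the thrombocyte, immediate early, oxidative stress, oxidative phosphorylation, ribosomal protein and proteasome lists, −0.646 for heat shock genes and 1.13 for inflammatory NF-kB genes. Its POLA2 difference between trials was 2.08 on the log2 scale, against a median of 0.557.

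Interferon response genes were lower in second trials in 8 of 8 birds (mean difference −0.435), with bird 8427 far from the others at −1.37. With 1 bird left out the mean difference nearest to 0 was −0.301, which argues against 1 bird setting it. Blood cell composition cannot be told apart: regression on the white cell and thrombocyte score left an intercept of −0.402, but that score went down in 4 of 8 birds and up in the others, so the regression could hardly move the mean (a reading set after the value was seen). After subtracting the mean of the ribosomal protein, proteasome and oxidative phosphorylation scores the difference was −0.13 (exact permutation p = 0.555, below 0 in 4 of 8 birds), as a general loss of housekeeping transcripts would give. Without the pair labelled 8439 it was −0.25 (7 pairs, exact permutation p = 0.25), a value that rests on bird 8427, since without both birds it was −0.101 of −0.235 and without 8427 alone 0.0155. In birds 8428, 8430 and 8436 the interferon score fell (−0.409, −0.254 and −0.386) while the housekeeping mean did not (0.0174, 0.0223 and 0.178). In the other birds both fell, and the mean housekeeping difference of −0.305 owes much to 8439 (−1.41). The prediction set beforehand for the housekeeping explanation was met over 8 birds. Reading the 7 birds as well, a rule set after the first value was seen, leaves it open, so it cannot be told apart from a change of interferon genes alone. An effect of recapture or of a second playback stays open and untested, since no bird was sampled repeatedly without playback.

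Other values lay apart within their groups. Baseline bird 8448 was high in T cell score (3.16 mean log2 CPM when scored with the local song libraries), CD8A (19.2 CPM), YWHAH (30.6 CPM), proliferation score (1.43) and inflammatory NF-kB score (3.04). Baseline bird 8435 was low in circadian clock score (3.33), bird 8438 high in SLC44A1 (13.5 CPM), and bird 8450 high in MN1 (5.93 CPM). Interferon genes in bird 8427 also stood at −1.37 between foreign and local song, the same pair of libraries. In all, 31 of 98 groups of values had such a value. A rate of 1 in 20 gives about 5, but holds only for normal values in groups not picked by those values. SHROOM2, SIK2, NSG1, SGO1 and CD8A were named from differences that 1 baseline bird largely set. The groups also overlap, since 1 library enters many of them, so the excess over 5 is not a test.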

How the results depend on the processing

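Fits that removed the 3 most abundant genes, list tests without each bird, named gene values without the pair labelled 8439, and fits against baseline that left out the library labelled 8439, the libraries labelled 8439 and baseline 8450, baseline bird 8448, each library in turn, or the 4 libraries apart on the first 2 components (local song 8428, 8437 and 8439, baseline 8450) were chosen after seeing the data. Unless a value shows it, the cause of a difference was not tested.

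The bird block changed no gene count between songs or trials: without the replicate block 0 genes passed in the 16 paired libraries or in all 23 song libraries (edgeR; 255 and 320 at an unadjusted p under 0.05 between songs, 340 and 507 between trials), and 10 and 9 lists were called. Leaving out each bird in turn gave 0 genes in both comparisons (224 to 1213 at an unadjusted p under 0.05 between songs, 302 to 1412 between trials), 3 to 12 lists between songs and 7 to 10 between trials. Every other edgeR or limma-voom alternative gave 0 genes too, with 108 to 1665 and 100 to 2136 at an unadjusted p under 0.05. DESeq2 with the block called 4 genes between songs and 6 between trials. Camera with an estimated correlation and fry called 0 lists in each of the 4 comparisons. In the alternatives, camera with an estimated correlation called 2, heat shock genes for local song against baseline in first trials (0.0388) and without the 4 libraries apart (0.032).

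For foreign song against baseline the file note as a covariate gave 2 genes (edgeR) and DESeq2 1, and the others 0 (279 to 1662 genes at an unadjusted p under 0.05); 7 lists were called without the libraries labelled 8439 and baseline 8450, and 7 without baseline 8450 alone, against 4; of the 4 libraries apart only that one is in this comparison. For local song the count of 1 gene became 0 in first trials, in 1 fit over all 33 libraries, with the file note, with DESeq2 size factors, without a filter, with the strict filter (ENTPD1 is below its minimum), without the libraries of 2 lanes, without the 3 most abundant genes and without the library labelled 8439 (294 to 1930 genes at an unadjusted p under 0.05). It became 18 with DESeq2, 3 without the libraries labelled 8439 and baseline 8450 (EFCAB5, ENTPD1 and MN1), and 9 without the 4 libraries apart. First trials called 10 lists against 6. Without baseline bird 8448 the counts were 0 and 1 genes and 3 and 6 lists. Leaving out each library in turn gave 0 genes and 3 to 7 lists for foreign song (598 to 1346 genes at an unadjusted p under 0.05), and 0 to 2 genes and 4 to 9 lists for local song (569 to 1447).

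Signs of named genes turned as follows. Between songs without the replicate block in all 23 libraries, PLS1 stood at −0.17, SFXN1 at −0.28, CD8B at 0.064 and HSPA2 at −0.011; with the marker covariate BCL11B stood at 0.035, PSMG1 at −0.059 and GATA2 at 0.30, and without stimuli 5 and 6 GATA2 at 0.055. In first trials PLS1 was at −0.67, SFXN1 −0.987, EPAS1 −0.58, IQGAP3 0.15, TFRC −0.25, UROS −0.18, ALOX5AP 0.016, BCL11B 0.0023, CD8B 0.63, CD40 0.50, EBF1 0.29, HSPA2 −0.70 and DNAJB4 −0.22. Against baseline VPREB3 after foreign song was at 0.19 with DESeq2, 0.20 without the libraries labelled 8439 and baseline 8450 and 0.17 without baseline 8450 alone. ALOX5 after local song was at 0.16 with DESeq2, 0.037 with the marker covariate and 0.18 without baseline bird 8448. The other 1614 values of named genes kept their sign, and no sign turned between trials. ENTPD1 after local song stayed between 0.95 and 1.29 in the fits that lost its call.

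The strict filter moved the median log2 fold change between songs by −0.116 over the genes it kept. Own-pair likeness was 0.53 over the 1000 most abundant genes and 0.565 without the pair labelled 8439. The share of the 10 most abundant genes differed by −0.23 and 2.63 percentage points from baseline in first trials, and by −2.21 between songs without the pair labelled 8439. Removing haemoglobin genes was not run, because no gene row carries a haemoglobin symbol. No fit was made at a lower depth. The common biological coefficient of variation was 0.351 within birds, 0.499 for foreign song against baseline and 0.535 for local song against baseline, and simulated 1.5-fold changes were mostly missed.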

Other observations

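The split counts were planned before the results were seen, but the number of splits drawn was lowered for running time after counts from more draws had been seen, which read the same way. The genes named for single birds were chosen after their values were seen.

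Single song birds carried high levels of genes that stood at least 20 times lower in every other bird. DRD4, a dopamine receptor, was at 11.4 CPM in the local song library of bird 8432, and TPD52L1 at 71.0 CPM in the foreign song library of bird 8433; each of these birds has 1 library. ESX1, a homeobox gene, stood at 15.5 CPM after foreign and 16.7 CPM after local song in bird 8436 and at no more than 0.0564 CPM in any other bird, and OPN3, an opsin, at 16.4 and 13.2 CPM in bird 8427 against at most 0.123. Among baseline birds CEP170B reached 85.8 CPM in 8447 and FLVCR1, a haem exporter, 35.0 CPM in 8448. ATP11A (14.5 against 0.174 CPM) and VWA5B1 (8.58 against 0.0521 CPM) were high in the local song library labelled 8439 and near 0 in its foreign song partner.

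Other groupings of the same libraries were tested in the same way, by swapping labels within birds or re-dividing libraries between groups. A swap changed the tested label alone and kept the other term, so many swaps tied song to trial, which the real grouping balances. The swap counts therefore come in part from designs unlike the real one. The 3 gene counts of 0 cannot be tested in this way, since every split reaches 0 (highest other 686 between songs, 162 between trials and 3 for foreign song against baseline). With the real grouping counted among them, 23 of 40 swaps called at least the real 8 lists between songs (highest other 13) and 22 of 40 the real 8 between trials (highest other 12). Counted in the same way, 50 of 60 splits called at least the real 4 lists for foreign song against baseline (highest other 10), and for local song 4 of 60 called the real 1 gene (highest other 352) and 42 of 60 the real 6 lists (highest other 11). Chance was not excluded for these 5 results. Groupings that called 686, 162 and 352 genes may point to a structure of the samples other than the groups. This was not tested, and an outlying library or chance could give them too. For the swaps that called 686 and 162 genes, a tie of song to trial could do so as well.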
